A study of Homo sapiens with 8 samples.

How the data were processed

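The data are peak lists from ATF4 chromatin immunoprecipitation followed by sequencing, 1 list per library, for the cell lines Nalm6 and SUPB15 with and without L-asparaginase (1 IU/ml, 2 h). Each immunoprecipitation used 5 ug of antibody, per the labels. Samples were grouped by cell line and treatment from their titles, which also give the replicate number, with 2 libraries in each of the 4 groups.

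Reads were aligned with BWA to hg19 and peaks called with MACS2, and DiffBind was used, as far as the submitters' processing notes name these tools and this build; their versions and options are not given in the sources used here. The peaks were called per sample, since each deposited list belongs to 1 library. For each peak the deposited lists give a fold enrichment at the summit, which is a ratio of fragments to local background computed by the authors' peak caller, and −log10 p and −log10 q values, as deposited by the authors. The lowest −log10 q in the lists was 1.31 to 1.63. All listed peaks lay on the 22 autosomes or on chromosomes X and Y, and the display score was not used. Fold enrichments and −log10 values were used to describe, rank and filter peaks within a list.

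Peaks of the 4 lists of a line that share at least 1 bp were merged into regions. A region was called gained when both asparaginase lists and neither untreated list held a peak in it, and untreated-only in the opposite case. The other pairs of libraries were counted in the same way, and, after the data had been seen, with equally long lists too. For both lines together, the 8 lists were merged, and gained in Nalm6 was set against gained in SUPB15 by Fisher's exact test over regions with at least 1 peak of each line. Peak numbers were compared on the log2 scale by exact two-sided permutation tests, within each line and with labels permuted within each line over both. A line gives 6 arrangements and both lines 36, so that p cannot go below 0.333 and 0.0556. For the difference between the lines, p cannot go below 0.333 when every asparaginase list of both lines is longer than its untreated lists. The rule for the regions named was, per line, the 10 gained regions with the highest value of the lower fold enrichment of both asparaginase lists and 5 untreated-only regions chosen likewise, and the 10 regions gained in both lines with the highest value of the lowest of the 4 asparaginase enrichments. These tests and rules, and the alternatives of stricter q thresholds, equal list lengths, summit distance, reciprocal overlap, region width, left-out replicates and a replicate block, were set before the data were examined.

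The lists give no read totals. MACS2 computes the fold as (pileup + 1) / (background + 1) and p from a Poisson distribution, so the pair of values was solved for the whole-number pileup at the summit and the local background. This succeeded for 100% of the peaks of every list, with a tolerance of 0.001 in −log10 p. The lowest background in a list was taken as its genome background and used as the relative depth. All higher backgrounds were multiples of 0.02, with a tolerance of 0.0005. Such steps are what a background taken from the immunoprecipitated library itself gives, so the peaks appear to have been called without a control library; this is an inference from the values and is not stated in the labels. Without a control, copy number and open chromatin can raise peaks. Intervals on shares of regions are 95% Wilson intervals and cover counting error only.

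Further steps were chosen after the lists had been seen. At regions with a peak in all 4 libraries of a line, summit pileups plus 1 were divided by the genome background, taken as log2, centred on the median change between treatments and compared with limma (trend, Benjamini-Hochberg adjustment at 0.05). Overlaps were compared with those of positions shifted 10 times by 200 to 1000 kb. The inversion, the region classes and the limma comparison were tested on simulated data, and the shifted overlaps were not. The inversion recovered 100% of 20000 simulated pairs, and the number of gained regions found was 99.5% of the simulated number. Presence of a peak was simulated at random, whatever its strength. That share therefore does not show how weak peaks near the calling threshold are classed. With limma, changes of 2-fold and 4-fold were recovered at 42% and 95% of the altered regions in Nalm6 (25213 regions) and at 70% and 99% in SUPB15 (4765 regions). The altered regions were drawn only from those above the median strength, with a fixed spread and no shift between replicates. These shares therefore do not give the recovery over all regions of the real libraries. Only regions that were listed in all 4 libraries enter the limma comparison, so regions gained from below the calling threshold are not in it.

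The planned shares of regions near promoters, the 20 gene lists, the count of ATF4 binding elements and the peak strength at genes named in advance were not computed, since neither the sequence nor an annotation of hg19 was used here. The gene table at hand is of another build, GRCh38.p14, and its coordinates were not used. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.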

Results

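Chromatin immunoprecipitation with an antibody against ATF4, followed by sequencing, was carried out in the acute lymphoblastic leukaemia cell lines Nalm6 and SUPB15. ATF4 is a transcription factor of the integrated stress response whose translation increases when amino acids run short. L-asparaginase, a leukaemia drug, is an enzyme that breaks down asparagine. Cells were left untreated or received 1 IU/ml of L-asparaginase for 2 h, and the comparison asks where ATF4 was bound with and without the drug. Each of the 4 groups held 2 libraries, 8 in all, with 1 deposited list of peaks per library. For Nalm6 the series' design text speaks of independent experiments, and an experiment per condition beyond these 2 was not analysed here. For SUPB15 nothing says that the libraries came from separate cultures, so differences between these samples may be technical. Permutation p-values treat the libraries as units. Fisher p-values count regions, and limma p-values take the spread of a region partly from other regions. Positions are in the hg19 build. Regions carry no gene names, because no annotation of that build was used here.

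The lists held 34825 and 36801 peaks for untreated Nalm6 and 43376 and 48984 for Nalm6 with asparaginase. For SUPB15 they held 9575 and 9586 peaks without treatment and 88302 and 41213 with asparaginase. Relative sequencing depth was read from the genome background, the number of fragments per position that a peak-free genome would show. It was 2.97 and 2.79 in untreated Nalm6, 2.21 and 2.33 in Nalm6 with asparaginase, 4.08 and 3.90 in untreated SUPB15, and 4.19 and 3.93 in SUPB15 with asparaginase. Lists of the same group overlapped to different degrees. Of the peaks of Nalm6 asparaginase replicate 1, 88.3% overlapped a peak of replicate 2, and 77.2% did so the other way. For the untreated Nalm6 libraries these shares were 84.0% and 79.2%. In SUPB15, 51.9% and 52.0% of the untreated peaks had a partner, and with asparaginase 30.7% of the peaks of replicate 1 and 67.6% of those of replicate 2.

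**Figure D1:**
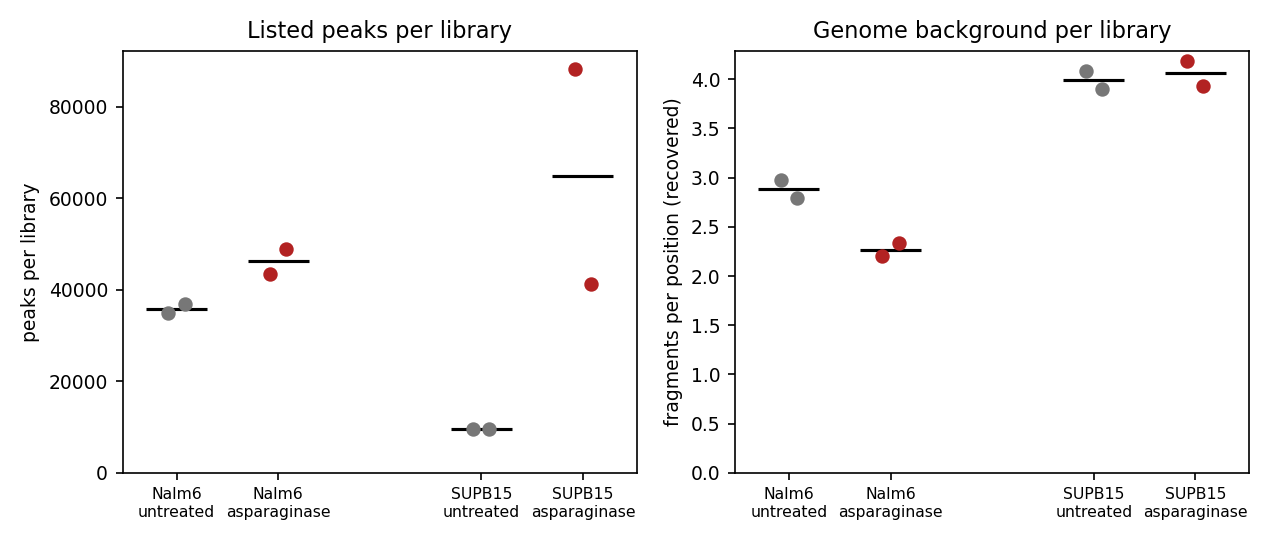
Points are single libraries and black lines are the means of 2 libraries. The left panel gives the number of listed peaks per library and the right panel the genome background in fragments per position. Peak numbers were higher with asparaginase in both lines, while the background was lower with asparaginase in Nalm6 and overlapped between groups in SUPB15.

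In Nalm6, 7040 regions were gained with asparaginase, which means that both asparaginase lists held a peak there and neither untreated list did. The opposite class, with a peak in both untreated lists only, held 694 regions. A peak was present in all 4 libraries at 25213 of 57175 regions, and 91.3% of the regions found in both untreated lists were also in both asparaginase lists. The gained region of highest fold enrichment lay on chromosome 7 from 76108740 to 76109434. Its enrichment over local background, the peak caller's value, was 20.5 in both asparaginase lists. At its summit 76 and 81 fragments were piled up, 34.4 and 34.7 times the genome background of those libraries.

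The next regions in Nalm6 were on chromosome 15 from 34190533 to 34191075 (fold enrichment 15.3 and 16.6), on chromosome 5 from 143261801 to 143262714 (15.6 and 15.3), on chromosome 15 from 49550384 to 49551033 (14.5 and 13.8) and on chromosome 17 from 35725520 to 35726071 (14.5 and 13.3). They were followed by regions on chromosome 1 from 26813657 to 26814258, chromosome 4 from 9849794 to 9850534, chromosome 10 from 133275517 to 133276261, chromosome 3 from 139917590 to 139918479 and chromosome 17 from 76028870 to 76029548, where the lowest enrichment was 12.0. The untreated lists named none of these 10 regions, although at genome background they listed peaks from 3.37 and 3.94 times that background upwards. A higher local background raises that limit, so the absence of a listed peak is not a measured level of 0.

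Gained regions in Nalm6 were narrower and weaker than regions with a peak in all 4 libraries. Their median width was 395 bp against 890 bp, and the median of the lower fold enrichment of both asparaginase lists was 4.50 against 5.58. Both differences are partly built into the classes. Merging peaks of more lists widens a region, and absence from both untreated lists selects weak sites. In 1689 gained regions, 24.0%, −log10 q reached 10 in both asparaginase lists. The strongest untreated-only region, on chromosome 5 from 49436957 to 49437310, had enrichments of 6.11 and 7.02. The other 4 named ones were on chromosome 14 from 77647870 to 77648863, chromosome 6 from 25070905 to 25071342, chromosome 3 from 197381082 to 197381321 and chromosome 10 from 93471897 to 93472427, with lower enrichments of 4.91 to 5.53. Without asparaginase replicate 1, 14358 regions counted as gained. Without untreated replicate 1, untreated replicate 2, asparaginase replicate 1 or asparaginase replicate 2, the untreated-only class held 3420, 3009, 1168 and 1925 regions, and with equally long lists of strongest peaks the classes held 4304 gained and 2122 untreated-only regions.

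**Figure D2:**
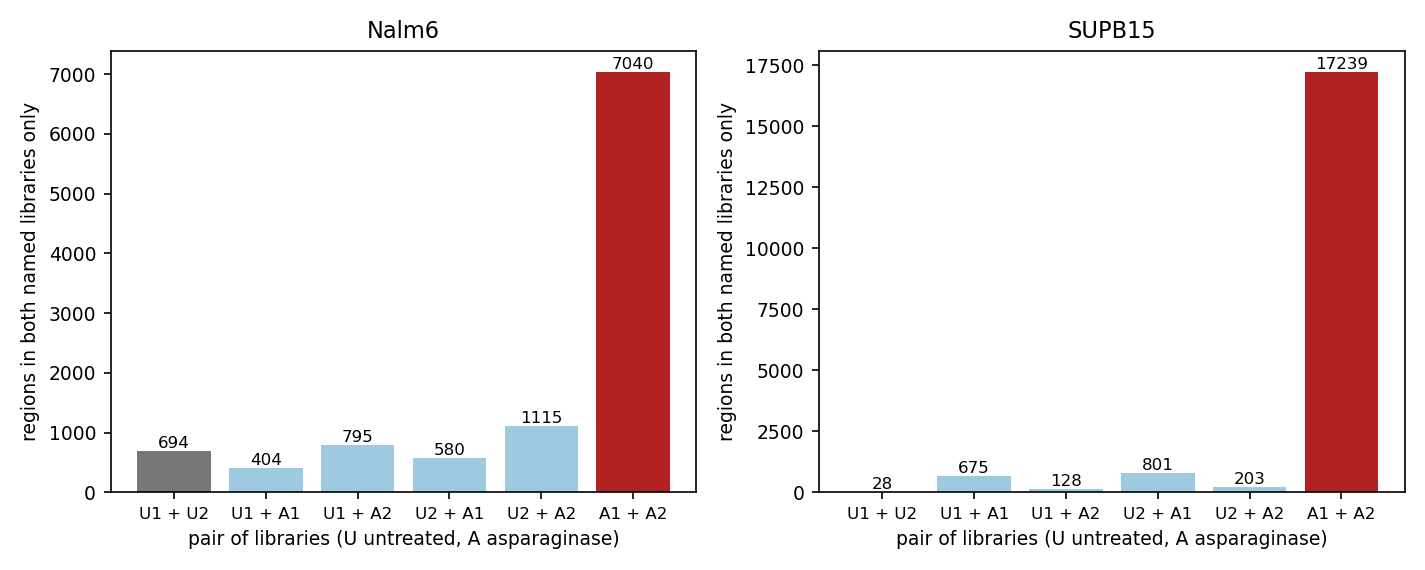
Bars count merged regions with a peak in the 2 named libraries and in neither of the other two of that line, for each of the 6 pairs (U, untreated; A, asparaginase). The gained pair A1 + A2 was the highest in both lines, with 7040 and 17239 regions, against 404 to 1115 and 128 to 801 for the mixed pairs; the asparaginase lists were also the longest.

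A pair made of an untreated and an asparaginase library of Nalm6 had 404 to 1115 regions to itself. The asparaginase lists were the longest, which by itself favours their pair. With equally long lists of strongest peaks, counted for mixed pairs after the data had been seen, mixed pairs had 455 to 537 regions to themselves, beside the 4304 gained and 2122 untreated-only regions. These counts carry no test. The number of peaks was 46180 ± 3965 (SD, n = 2) with asparaginase against 35813 ± 1397 (SD, n = 2) without, a ratio of geometric means of 1.29 (exact two-sided permutation test, p = 0.333, the smallest that 2 against 2 libraries allow).

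In SUPB15 there were 17239 gained regions and 28 untreated-only regions, and 4765 of 102989 regions had a peak in all 4 libraries. Gained regions made up 64.9% of the regions in both asparaginase lists, compared with 19.4% in Nalm6. The untreated SUPB15 lists were much shorter than those of Nalm6 and barred fewer regions, so these shares do not compare the responses of the lines. Of the regions found in both untreated lists, 94.8% were also in both asparaginase lists. The region of highest enrichment was on chromosome 6 from 102335506 to 102335873, with fold enrichments of 14.1 and 12.0 and summit pileups 17.2 and 14.8 times the genome background.

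The regions next in strength in SUPB15 were on chromosome 21 from 25303870 to 25304494 (fold enrichment 13.1 and 11.6), chromosome 10 from 114350481 to 114351043 (11.2 and 11.4), chromosome 2 from 58743085 to 58743775 (13.3 and 10.8) and chromosome 12 from 42048286 to 42048743 (14.1 and 10.7). The other 5 named regions were on chromosome 12 from 66052160 to 66052542, chromosome 7 from 91225167 to 91225564, chromosome 7 from 44013667 to 44014024, chromosome 12 from 102723581 to 102724171 and chromosome 7 from 87833759 to 87834429, with lower enrichments of 10.4 to 10.7. At genome background the untreated lists held peaks from 3.43 and 3.33 times that background upwards. The 5 strongest untreated-only regions, on chromosome 7 from 61988470 to 61988814, chromosome 14 from 31390565 to 31390899, chromosome 15 from 56296004 to 56296251, chromosome 22 from 17300144 to 17300616 and chromosome 19 from 48453131 to 48453451, had lower enrichments of 4.33 to 4.84.

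Most gained regions of SUPB15 were weak. The median of their lower fold enrichment was 3.50, against 6.03 at regions with a peak in all 4 libraries, and the median width was 410 bp against 765 bp. As in Nalm6, both differences are partly built into the classes. In 2406 of them, 14.0%, −log10 q reached 10 in both asparaginase lists. A further 59358 regions were listed in asparaginase replicate 1 alone and 12917 in replicate 2 alone. Without asparaginase replicate 1 or replicate 2, 30156 and 76597 regions counted as gained. The untreated-only count became 1262, 876, 203 and 87 without untreated replicate 1, untreated replicate 2, asparaginase replicate 1 and asparaginase replicate 2, and equally long lists of strongest peaks gave 2683 gained and 1036 untreated-only regions.

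Mixed pairs of SUPB15 libraries had 128 to 801 regions to themselves, and 134 to 252 with equally long lists of strongest peaks. The peak number was 64757.5 ± 33297 (SD, n = 2) with asparaginase and 9580.5 ± 7.78 (SD, n = 2) without, and the ratio of geometric means was 6.30 (exact two-sided permutation test, p = 0.333, the smallest possible). Over both lines the peak number was 2.85 times as high with asparaginase. With labels permuted within each line the exact two-sided p was 0.0556, again the smallest that these 8 libraries allow. The response of SUPB15 exceeded that of Nalm6 by 2.29 on the log2 scale (exact permutation test, p = 0.333). In both lines every asparaginase list was longer than every untreated list. The test cannot give a smaller p in that case, so it does not bear on whether the lines differ.

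The lines shared part of their gained regions. With all 8 lists merged, 24480 regions held a peak of each line, and 1678 of these were gained in both lines. Lists gained independently of each other would have given 1030. Over the 8 lists 7017 regions were gained in Nalm6, and 3422 of them held a SUPB15 peak. Of these 3422, 49.0% (95% Wilson interval 47.4 to 50.7) were gained in SUPB15 too, against 27.0% (26.4 to 27.6) of the other 21058 regions. Among those 21058, at least 3994 could not be gained in SUPB15, as they had a peak in both untreated lists of both lines. A peak in either untreated SUPB15 list already bars a region, and the regions barred in that way were not counted. Barred regions lower the share of 27.0% by definition, which can raise the odds ratio. They can also lower the count of 1030 for independent lists. A comparison among regions that could be gained in both lines was not run. The odds ratio was 2.60 (95% interval 2.42 to 2.80; Fisher's exact test, two-sided, p = 9.37e-140), a test over regions, which are not independent replicates. Without SUPB15 asparaginase replicate 2 the count was 2575 and the odds ratio 2.26. With equally long lists of strongest peaks the count was 554 and the odds ratio 4.77.

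Among regions gained in both lines, the highest value of the lowest enrichment was found on chromosome 3 from 34152249 to 34153025. Fold enrichments there were 9.60 and 9.75 in Nalm6 and 8.93 and 8.78 in SUPB15. On chromosome 4 from 59600391 to 59600882 they were 9.62 and 8.79 in Nalm6 and 10.6 and 8.73 in SUPB15, and on chromosome 1 from 224811318 to 224812118 they were 9.12 and 8.71 in Nalm6 and 9.16 and 8.71 in SUPB15. The region on chromosome 7 that led the Nalm6 list, from 76108740 to 76109549 when merged over both lines, was among the 10, with 9.83 and 8.32 in SUPB15. The region on chromosome 17 from 35725520 to 35726071 was also in both sets and reached 10.5 and 8.53 in SUPB15. The remaining 5 were on chromosome 2 from 18266718 to 18267249, chromosome 3 from 59545372 to 59545979, chromosome X from 44087695 to 44088162, chromosome 22 from 21307963 to 21308871 and chromosome 2 from 134433779 to 134434487, where the lowest enrichment was 7.67 to 8.65.

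Other regions were gained in a line without a counterpart. No library of Nalm6 had a peak at 9609 regions gained in SUPB15 (56.6%), and no library of SUPB15 had a peak at 3595 regions gained in Nalm6 (51.2%). At 3871 regions gained in SUPB15, 22.8%, all 4 Nalm6 libraries held a peak, both untreated ones included. A peak was found in all 8 libraries at 3812 regions. Of the 5055 regions in both untreated SUPB15 lists, 79.0% were in both untreated Nalm6 lists.

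**Figure D3:**
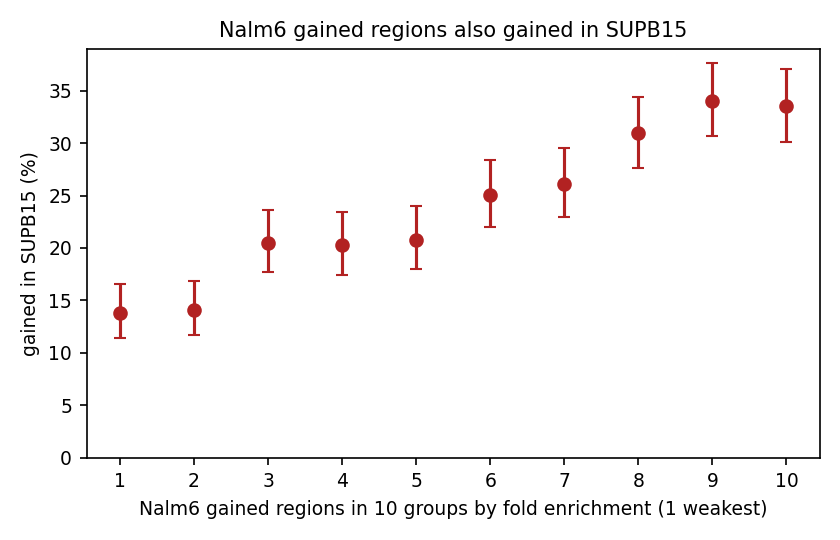
The horizontal axis gives the Nalm6 gained regions in 10 groups of 701 or 702, ordered by the lower fold enrichment of both asparaginase lists, and the vertical axis the percent gained in SUPB15 with 95% Wilson intervals. The share was 13.8% in the weakest group and 33.5% in the strongest.

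Among all 7017 Nalm6 gained regions over the 8 lists, the share gained in SUPB15 differed with their strength. It was 13.8% (95% Wilson interval 11.5 to 16.6) in the weakest 702 regions, with enrichments of up to 3.30, and 33.5% (30.1 to 37.1) in the strongest 701, with enrichments from 6.96. Of the strongest 701, a further 80 regions had a peak in both untreated SUPB15 lists and therefore did not count as gained there, compared with 7 of the weakest 702. Regions with a peak in only one untreated SUPB15 list were barred as well and are not in these numbers. These intervals cover counting error over regions only.

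Peaks of SUPB15 were concentrated on parts of chromosomes 1 and 8, which were chosen after the lists had been seen. Chromosome 8 from 60 Mb held 792 and 1340 of the untreated SUPB15 peaks, 8.27% and 14.0%, and 9724 and 5429 of those with asparaginase, against 2.13% to 2.31% in the Nalm6 lists. Chromosome 1 from 180 Mb held 4.76% and 6.79% of the untreated and 6.44% and 6.81% of the asparaginase peaks of SUPB15, against 2.59% to 2.62% in Nalm6. On chromosome 8 the 5 Mb from 75 Mb held 119 and 274 of the untreated SUPB15 peaks, 1.24% and 2.86%, and 10 and 8 of the untreated Nalm6 peaks. Both whole segments together, chromosome 8 from 60 Mb and chromosome 1 from 180 Mb, held 3586 or 20.8% of the regions gained in SUPB15 (95% Wilson interval 20.2 to 21.4), against 520 or 10.9% (10.1 to 11.8) of the regions with a peak in all 4 libraries. Without chromosomes 1 and 8, SUPB15 had 12445 gained and 17 untreated-only regions.

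**Figure D4:**
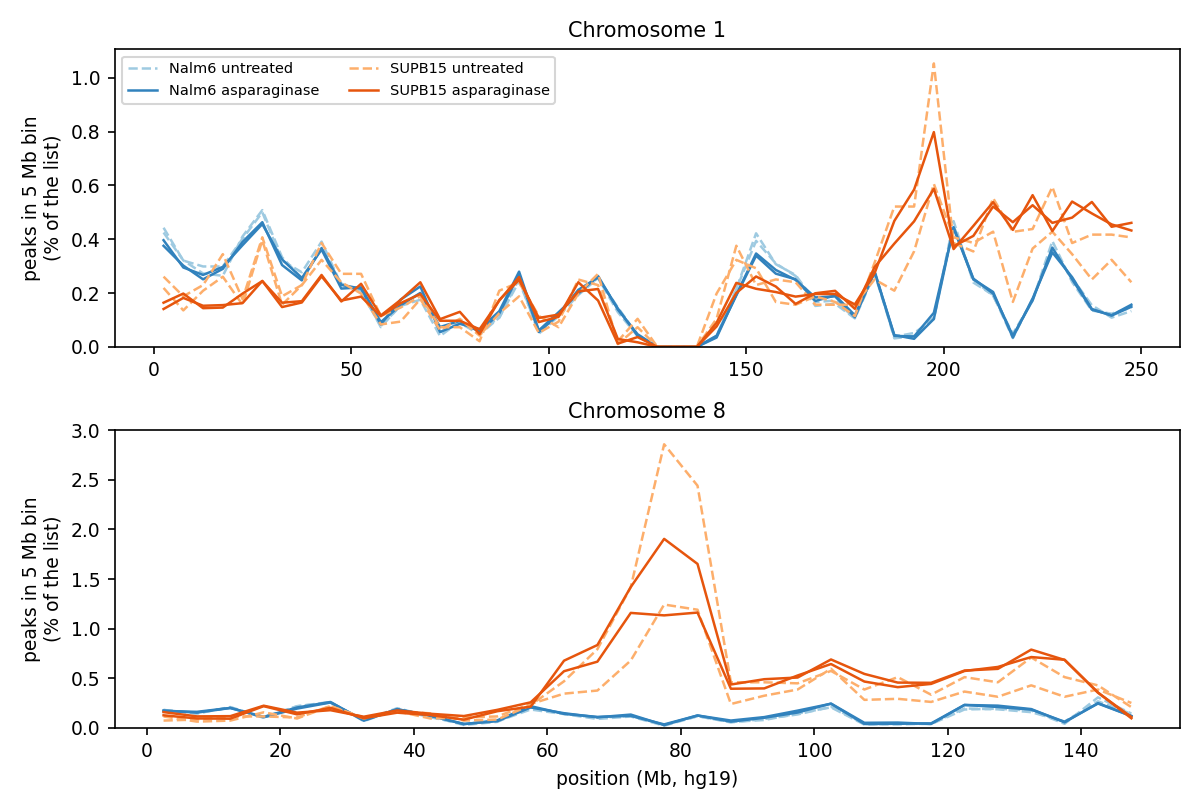
Lines give the percent of each list's peaks in bins of 5 Mb along chromosomes 1 and 8, by position in hg19, with 2 lines per group. In both untreated and both asparaginase lists of SUPB15, chromosome 8 from 60 Mb held 8.27% to 14.0% of the peaks, against 2.13% to 2.31% in the lists of Nalm6. The vertical scales of the panels differ.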

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

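The settings that require −log10 q of 10 for presence only, or leave out chromosomes 1 and 8, mixed pairs at equal lengths, and all settings of the summit pileups, were chosen after the data had been seen. Peak numbers stayed higher with asparaginase under every alternative run. Without single libraries the ratio was 1.21 to 1.37 in Nalm6, 4.30 to 9.22 in SUPB15 and 2.35 to 3.44 over both lines, and the difference between lines was 1.74 to 2.84 on the log2 scale. With −log10 q of at least 10 the ratios were 1.42 and 4.63. No p-value can pass 0.05 in these designs, so p says nothing about stability. Gained regions outnumbered untreated-only regions under every alternative, but their number moved with the threshold. With −log10 q of at least 5, Nalm6 had 450 untreated-only and SUPB15 9702 gained regions. With at least 10, there were 407 untreated-only regions in Nalm6, 4573 gained and 17 untreated-only in SUPB15, and 978 gained in both lines. With the same number of strongest peaks per list, 34825 in Nalm6 and 9575 in SUPB15, there were 4304 gained and 2122 untreated-only regions in Nalm6, 2683 and 1036 in SUPB15, and 554 gained in both. Equal lengths cut the longer asparaginase lists, which by construction removes gained and adds untreated-only regions. Summits within 200 bp gave 1505 and 154 untreated-only regions, and reciprocal overlap by 50% gave 2174 and 538; the cause was not tested. Presence at −log10 q of at least 10 with absence from the full lists left 1689 gained and 4 untreated-only regions in Nalm6, 2406 and 2 in SUPB15, and 266 gained in both, as fewer peaks can count. Without chromosomes 1 and 8 SUPB15 had 17 untreated-only regions. Leaving out a library relaxes the definition: gained regions were then 8565 to 14358 in Nalm6 and 19213 to 76597 in SUPB15, untreated-only regions 1168 to 3420 and 87 to 1262, and regions gained in both lines 1757 to 2575. The odds ratio for gain in both lines was 2.21 to 4.93 over the settings for which it was computed. No region was wider than 5 kb, so that limit moved nothing. The 10 named gained regions of each line kept their class with summits within 200 bp; stricter q and equal lengths could not move such strong peaks. At −log10 q of at least 10 only 1 of the 5 named untreated-only regions kept it in Nalm6 and 0 of 5 in SUPB15.

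With the replicate number as a block, the ratios of peak numbers remain 1.29 and 6.30 by construction, with smallest possible p-values of 0.5 within a line and 0.125 over both, and the region classes are identical (7040 and 17239 gained). The numbers are not shown to pair the samples. Deviations of same-numbered libraries from their group means correlated at 0.033 in Nalm6 and 0.086 in SUPB15 across regions, which are not independent replicates. For summit pileups at regions with a peak in all 4 libraries, the block gave 6396 higher and 3604 lower regions in Nalm6 and 1634 and 707 in SUPB15 (limma, adjusted p under 0.05), against 5717 and 2179, and 976 and 284, without it.

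Promoter shares, gene lists, binding elements and peak strength at genes, with their alternatives of distance, background and element, were not run. Depth is known only as a ratio between libraries.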

Other observations

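The comparison of summit pileups, the chromosome shares and the choice of the segments on chromosomes 1 and 8 came after the lists had been seen, and so did the comparisons of sequencing depth. The peak numbers at −log10 q of at least 10 and the odds ratio for gain in both lines were planned. The bounds by which these peak numbers and the depths are read below as tests of an explanation were set after the results were seen. A bound for the odds ratio was set then too, but the odds ratio decides nothing, for the reason given below.

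Signal also differed at regions that were listed without treatment. Of the 25213 regions with a peak in all 4 Nalm6 libraries, 5717 were higher and 2179 lower with asparaginase (limma, adjusted p under 0.05). The median change, 0.37 on the log2 scale, had been removed first. Limma estimates the spread of a region partly from all other regions, so small p-values do not rest on that region's 4 libraries alone. On chromosome 3 from 57703635 to 57704487 the summit pileup was 59.0 ± 1.48 times the genome background with asparaginase and 6.58 ± 0.688 times without (SD, n = 2), a centred log2 change of 2.80 ± 0.20 (SE; limma adjusted p = 4.88e-30). The next were on chromosome 4 from 152649340 to 152650388, with 58.8 ± 11.5 against 7.74 ± 3.34 times, chromosome 4 from 48976596 to 48977512, with 61.8 ± 3.55 against 8.36 ± 1.36 times, chromosome 2 from 177633544 to 177634247, with 66.7 ± 3.37 against 9.01 ± 0.579 times, and chromosome 16 from 33576637 to 33577714, with 38.2 ± 5.39 against 5.20 ± 0.259 times. The lower regions moved less. The strongest decrease, on chromosome 5 from 176073802 to 176074834, was from 24.1 ± 0.150 to 13.6 ± 3.22 times the genome background, a centred log2 change of -1.21 ± 0.21 (SE; limma adjusted p = 1.79e-07). Scaled by the genome background alone, 9762 regions were higher and 100 lower. Without asparaginase replicate 1 or 2 the lower regions were 583 and 684, with the spread taken from the untreated pair alone and the lone asparaginase library assumed to vary like it.

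In SUPB15, 976 of 4765 such regions were higher and 284 lower after a median change of 0.62 had been removed, and 2334 and 4 without that step. The strongest increase was on chromosome X from 70752655 to 70754088, from 5.64 ± 0.360 to 35.1 ± 7.80 times the genome background (SD, n = 2; centred log2 change 2.00 ± 0.36 SE, limma adjusted p = 4.91e-05), followed by chromosome 12 from 4524159 to 4524857, with 52.8 ± 13.8 against 9.37 ± 1.65 times. The strongest decrease was on chromosome 12 from 89602383 to 89603001, from 13.8 ± 4.69 to 6.43 ± 0.992 times. The counts changed when libraries were left out. With limma, 6 regions were higher and 4 lower without untreated replicate 1 (452 and 133 at unadjusted p under 0.05), and 0 and 0 without untreated replicate 2 (328 and 84 unadjusted). In both of these fits the spread came from the asparaginase pair alone, and the lone untreated library was assumed to vary like it. Without asparaginase replicate 1 there were 392 and 282, and without asparaginase replicate 2 there were 1063 and 596, with the spread from the untreated pair alone. Whether signal rose at regions already listed cannot be read from the ratio of higher to lower regions, 2.62 in Nalm6 and 3.44 in SUPB15, because removing the median change places as many regions above 0 as below it. Whether the Nalm6 regions that were higher among those with a peak in all 4 libraries are the ones gained in SUPB15 stays open. Of the Nalm6 regions that were higher, 22.2% were gained in SUPB15, against 15.6% of those that were lower and 13.9% of the rest, a ratio of 1.43 between the first 2 shares that met neither of the bounds set in advance.

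Peaks were more numerous with asparaginase in both lines. Deeper sequencing may be set aside as the reason, since the genome background with asparaginase was at most 1.02 times that without, and it was 0.788 times in Nalm6. Peaks close to the calling threshold do not account for all of it, because with −log10 q of at least 10 the peak number was still 1.42 times as high in Nalm6 and 4.63 times in SUPB15. Peaks with −log10 q below 10 made up most of the rise in SUPB15. The mean there was 64757.5 peaks with asparaginase against 9580.5 without, but 10499.5 against 2205 with −log10 q of at least 10. Most untreated SUPB15 peaks lay below 10 too. Only 26.3% and 19.7% of them reached it, against 15.2% and 18.5% with asparaginase. The ratio of peak numbers in SUPB15 was 6.30 over all peaks and 5.33 with −log10 q of at least 5. A stronger immunoprecipitation as a whole in the asparaginase libraries stays open. The median change at regions with a peak in all 4 libraries was 0.37 on the log2 scale in Nalm6 and 0.62 in SUPB15, and more ATF4 on chromatin would give the same shift. In Nalm6 the shift depends on dividing by a genome background that was 0.788 times as high with asparaginase. In SUPB15 the asparaginase replicates differed from each other by 0.37 at these regions, and the untreated ones by 0.13.

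SUPB15 peaks crowded on chromosome 8 beyond 60 Mb and chromosome 1 beyond 180 Mb. Binding specific to the treatment is not favoured, because the segments held 3.3% of the 1000 strongest gained regions (95% Wilson interval 2.36 to 4.60) and 29.1% of the 1000 weakest. Extra copies of these segments in SUPB15 may raise background and with it weak peaks, and this could not be settled. The median local background of the untreated peaks there was 1.13 and 0.996 times that on other chromosomes, which met neither bound set in advance, and listed peaks are no random sample of a segment.

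In SUPB15 with asparaginase, replicate 1 listed 88302 peaks and replicate 2 listed 41213. Depth does not explain this, as the genome background of replicate 1 was 1.07 times that of replicate 2. Chance calls stay open; regions listed in replicate 1 alone overlapped Nalm6 asparaginase regions 7.67 times as often as shifted positions did (12.3% against 1.61%), but such calls may gather at sites that can hold a peak, which shifted positions leave. A stronger immunoprecipitation in replicate 1 is a candidate explanation, with summit pileups 0.37 higher on the log2 scale at regions with a peak in all 4 libraries. No biological explanation was tested, because both libraries belong to the same group.

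Among regions with a peak of each line, 1678 were gained in both lines, against 1030 for independent gain (odds ratio 2.60). Whether gain was independent between the lines is not decided by this, because regions with untreated peaks stayed in the comparison. A region with an untreated peak of a line cannot be gained in that line, which can raise the odds ratio by definition. No test was run among regions that could be gained in both lines. Weak regions may be classed as gained in both lines more readily than strong ones, which the odds ratio does not take into account. Dropping weaker peaks did not lower it. It was 2.63 and 2.67 with −log10 q of at least 5 and 10, and 4.77 with equally long lists. With −log10 q of at least 10 required for presence only, it was 4.93, but weak regions that cannot reach that threshold stayed in the comparison. Each setting has a threshold of its own, so strength was still not matched. All settings also kept regions with untreated peaks, so these values do not decide whether weak regions account for the odds ratio. Shifted positions do not bear on shared gain. The 1689 overlaps between the gained regions of both lines were 30.2 times the highest number after shifting, but a shift moves regions away from sites that can hold a peak at all. A graded response shared by the lines is a hypothesis in line with the strongest 701 Nalm6 gained regions being gained in SUPB15 2.43 times as often as the weakest 702, although strong peaks may also be easier to detect in both lines.

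Gained regions of Nalm6 were spread unevenly over the 24 chromosomes, with 6 over- and 5 under-represented relative to regions with a peak in all 4 libraries (Fisher's exact test over regions, adjusted over both lines). Chromosome 19 held 2.40% of the gained and 5.44% of these regions (adjusted p = 1.79e-28), and chromosome 4 held 5.61% and 3.85% (adjusted p = 3.25e-09). In SUPB15, chromosome 8 was over-represented, with 15.8% and 8.31% (adjusted p = 1.95e-41), and 5 chromosomes were under-represented.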
